A study of Drosophila melanogaster with 4 samples.

How the data were processed

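Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for H3K36me2 in ML-DmBG3-c2 cells, a Drosophila melanogaster line that the labels derive from the larval central nervous system. The antibody was a mouse monoclonal, per the labels. The series holds 4 samples, of which 2 are ChIP replicates and 2 are input DNA replicates. Cells were fixed with formaldehyde and chromatin was sheared by sonication, per the labels' protocols. Samples were grouped by their titles and source names. The descriptions in the labels contradict these for some samples: ChIP replicate 1 is described as input DNA, and the descriptions of input replicate 1 and ChIP replicate 2 name both ChIP DNA and input DNA. Which is right was not tested.

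The deposited values are 3 lists of regions: one for each ChIP replicate and a combined list of the replicate set. Each region has a start, an end and a score. The score column was written by the authors' region caller, and its scale is not given in the sources used here. Scores were used to describe, rank and compare clusters within a list, and between the replicate lists by correlation; means of scores over the replicates are given with their SD as a description. Coordinates are on FlyBase r5, per the file headers. Bowtie 0.12.7 is listed in the submitters' processing notes. The region caller, its threshold, the read filters, the way the replicates were combined and the input used for each list are not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown, and no interval or detection limit that needs a depth was computed. Input libraries had no list of their own and enter only through whatever the authors' caller did with them.

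The lists differ in ways that affect the measurements. The shortest region in either replicate list is 1301 bp, whereas the combined list goes down to 1001 bp. The combined list also holds 16 regions named as depletion beside 6396 named as enrichment. The depletion regions were left out of every main comparison, were kept in an alternative only, and are described separately. An enriched region is called a cluster here. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. The p-values rest on the spread over blocks, clusters or shifted positions within these lists, and not on the spread between samples.

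Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9. The covered share of a sequence was the summed cluster length divided by the sequence length in the file headers. Overlap was counted from 1 bp. The overlap of the replicate lists was compared with 100000 sets of circular shifts of one list within each sequence, which keep cluster lengths and spacing (one-sided permutation test). Scores were matched by the largest overlap, and correlations were tested by 100000 permutations. X and the autosomal arms were compared by permuting the labels of 1 Mb blocks 100000 times (two-sided), with blocks under 0.5 Mb left out and Benjamini-Hochberg adjustment over the 4 measures compared. Clusters of one replicate only were compared with shared clusters by permuting that label 100000 times. Blocks and clusters are not biological replicates, and neighbouring ones are correlated, so these p-values describe the lists at hand. Shares of clusters carry 95% Wilson intervals, which cover counting error only.

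The overlap test and the block test of covered share were tried on simulated or shuffled values first. Independent simulated lists on arm 2L, with clusters placed at random, gave an overlap p under 0.05 in 2 of 50 draws. For the block test, the covered shares of the real blocks were shuffled. It gave p under 0.05 in 5 of 100 shuffles with no difference, and in 86 of 100 with 5 percentage points added on X. Random placement and shuffling remove the grouping of clusters and the correlation of neighbouring blocks. These rates therefore do not show how the tests behave with them.

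The rule for the regions named in the text was fixed before the data were examined: the 5 highest-scoring and the 5 longest combined-list clusters covered over at least 50% of their length in both replicates, the 5 longest cluster-free stretches of the arms, and the highest-scoring combined-list cluster of each arm. Where scores tied, each cluster is named. The tests of score, length and cluster density on X, the test of chromosome 4, the heterochromatic score test and the centromere test were chosen after the values were seen. Alternatives were the highest 50% of each list by score, a minimum length of 1 kb, merging of clusters less than 1 kb apart, an overlap of at least 50% of the cluster, the 5 large arms alone, blocks of 250 kb, each replicate alone and the combined list. Unplanned alternatives for the combined list were keeping the depletion regions and leaving out clusters shorter than 1301 bp.

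Comparisons of gene parts, of profiles along genes and of 25 gene lists fixed beforehand were not made. The gene table used here is on Release 6 of the genome, and coordinates were not carried between releases. Regions are therefore given by position, without gene names or annotation.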

Results

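H3K36me2 was mapped by ChIP-seq in ML-DmBG3-c2 cells, a cultured line from the third instar larval nervous system of Drosophila melanogaster. H3K36me2 is histone H3 dimethylated on lysine K36. The samples were 2 ChIP replicates and 2 input DNA replicates. The lists analysed were the enriched clusters of each ChIP replicate and of the combined replicate set. Read depths were unknown, because the lists give positions and the authors' scores without read counts. The score of a cluster is the authors' own value, and score levels of different lists were not tested against each other. The comparisons asked how far the replicates marked the same regions, and where in the genome those regions lay.

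H3K36me2 clusters were spread over all 5 large chromosome arms. Replicate 1 had 5554 clusters over 26.9 Mb and replicate 2 had 5583 clusters over 25.8 Mb, or 5568.5 ± 20.5 clusters (SD, n = 2). On arms X, 2L, 2R, 3L and 3R, which together measure 119.0 Mb, the covered share was 20.3% ± 0.600 (SD, n = 2). Most clusters were a few kilobases long, with a median of 3066 bp in replicate 1 and 2886 bp in replicate 2. Clusters of 10 kb or more made up 9.38% of the replicate 1 list and held 33.9% of its covered sequence, and the same class made up 8.67% of the replicate 2 list and held 32.4%. The longest cluster reached 76583 bp in replicate 1 and 55481 bp in replicate 2. Longer clusters had higher scores, with Spearman's rho across clusters of 0.83 in replicate 1 and 0.84 in replicate 2. The combined list held 6396 clusters over 29.9 Mb.

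The replicates marked largely the same sequence. They shared 23.9 Mb, which was 88.8% of the sequence covered in replicate 1 and 92.8% of that in replicate 2, for a Jaccard index of 83.0%. Circular shifts of one list gave 5.37 ± 0.213 Mb (SD over 100000 shifts) and at most 9.50 Mb, so the observed overlap was 4.45 times the shifted mean (one-sided permutation p = 1e-05, the smallest these shifts can give). Of the replicate 1 clusters, 4944 overlapped a replicate 2 cluster, or 89.0% (95% Wilson interval 88.2 to 89.8%), against 32.2% after shifting. Of the replicate 2 clusters, 5061 overlapped a replicate 1 cluster, or 90.7% (89.9 to 91.4%). Most boundaries were placed closely: among 4831 pairs that were each other's best match, the median distance was 117 bp between starts and 122 bp between ends. Of these pairs, 66.7% had starts and 65.7% had ends within 200 bp, and the rest lay further apart. Whether the lists were called against the same input is not given in the sources used here.

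Clusters with high scores in one replicate had high scores in the other. Across the 4944 matched clusters, Spearman's rho was 0.92 and Pearson's r was 0.93 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Clusters are not independent replicates, and the p-values refer to this pair of lists.

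**Figure D1:**
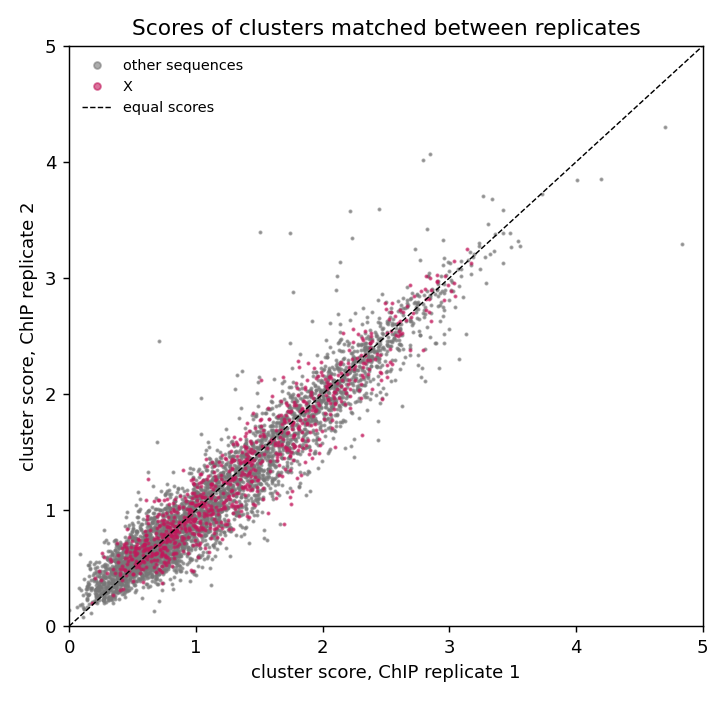
Authors' score of each cluster in ChIP replicate 1 (x axis) against its best-matching cluster in ChIP replicate 2 (y axis), 1 point per pair, with clusters on X in a second colour and a dashed line of equal scores. The 4831 pairs lie along the line, with a few pairs far above or below it.

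The clusters found in a single replicate were shorter and lower in score than shared clusters by their medians. Replicate 1 had 610 clusters with no overlap in replicate 2, or 10.98% (10.2 to 11.8%), and replicate 2 had 522 without overlap in replicate 1, or 9.35% (8.61 to 10.1%). Their median length was 1799 bp in replicate 1 and 1646 bp in replicate 2, against 3332.5 bp and 3139 bp for shared clusters. Their median scores were 0.53 and 0.40, against 1.09 and 1.03. The differences in mean length and mean score passed the two-sided permutation test in each replicate (adjusted p = 1e-05 for each of the 4 tests, the smallest that 100000 permutations can give). There were exceptions: clusters of replicate 1 only reached a score of 4.48 and a length of 17397 bp, and those of replicate 2 only reached 2.76 and 8903 bp. Among the lowest 25% of scores, 28.2% of replicate 1 clusters and 30.97% of replicate 2 clusters were unshared. Among the highest 50% of scores, 1.62% and 0.752% were unshared.

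Chromosome 4, the small and largely heterochromatic autosome, had the highest covered share of the sequences in the lists. Clusters covered 38.7% ± 0.922 of it (SD, n = 2), at 63.2 ± 1.57 clusters per Mb. The large arms were covered over 23.4% ± 0.476 on 2R, 20.8% ± 0.459 on 3R, 19.8% ± 0.958 on X, 19.1% ± 0.520 on 2L and 18.8% ± 0.613 on 3L (SD, n = 2 for each). In 250 kb blocks, chromosome 4 averaged 40.6% ± 12.9 (SD over 5 blocks) and arms 2L, 2R, 3L and 3R averaged 20.4% ± 12.6 (SD over 387 blocks), a difference of 20.2 percentage points (two-sided permutation p = 0.00087). The 5 blocks lie side by side, and the test treats them as independent. A single stretch of a large arm, 2R from position 1 to 1000000, was also covered over 38.7%. Among the large arms, the differences in covered share did not exceed the spread of their 1 Mb blocks (119 blocks, permutation p = 0.14).

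**Figure D2:**
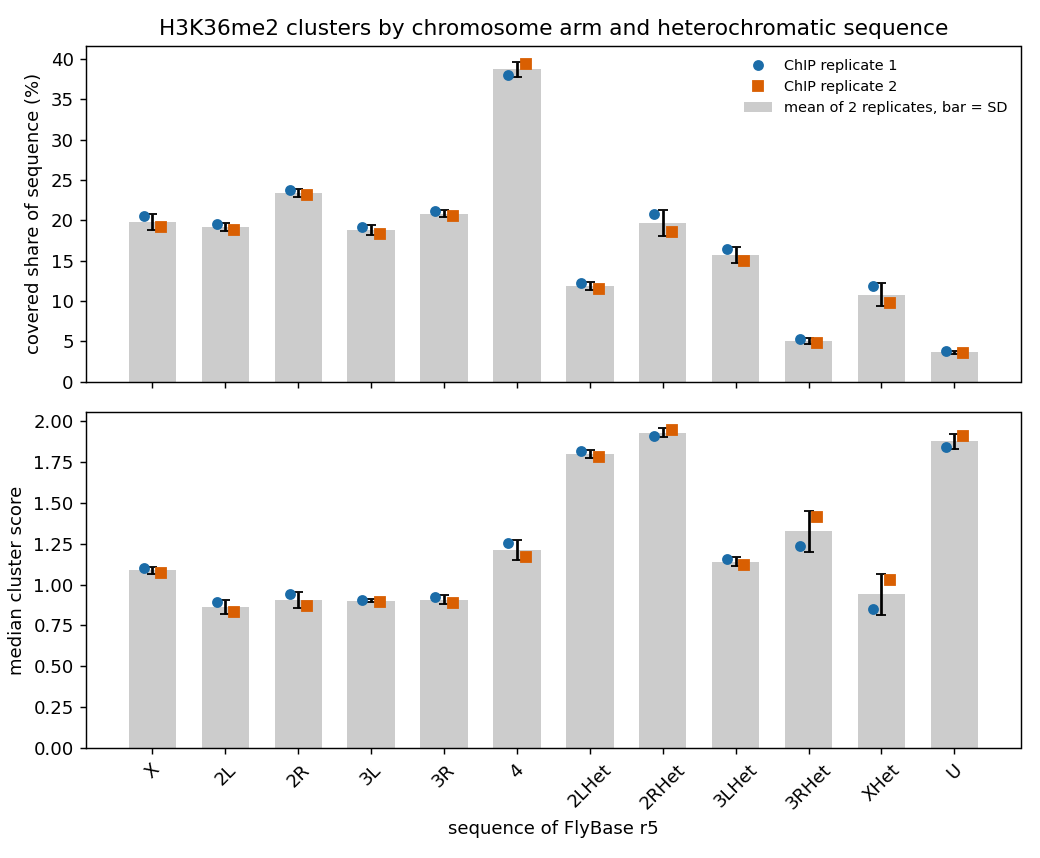
Covered share in percent (upper panel) and median cluster score (lower panel) for each sequence of FlyBase r5 with a replicate cluster on the x axis. The Y heterochromatin, without one, is left out. Bars are means of the 2 ChIP replicates, error bars are SD, and points are the replicates. Chromosome 4 has the highest covered share at 38.7%, and 2RHet has the highest median score at 1.93.

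Clusters on X had higher scores than clusters on the autosomal arms, and no difference in covered share passed the test. Across 1 Mb blocks, X was covered over 19.9% ± 5.35 (SD over 22 blocks) and the autosomal arms over 20.4% ± 7.51 (SD over 97 blocks), a difference of -0.48 percentage points that did not pass the two-sided permutation test (adjusted p = 0.92). Clusters per Mb (43.5 on X and 43.8 on autosomes) and median length (3054 bp and 3088 bp) did not pass the permutation test either (adjusted p = 0.92 for each). Split at the autosomal median score, X had 16.2 ± 3.97 clusters per Mb below it against 21.9 ± 7.45 on the autosomal arms (SD over blocks, permutation test, adjusted p = 0.0012). Above it, X had 27.3 ± 6.72 against 21.9 ± 7.38 (permutation test, adjusted p = 0.0022). At these total densities the split restates the score difference and is not separate evidence of it. The median score of a block averaged 1.09 ± 0.09 on X and 0.91 ± 0.14 on the autosomal arms, a difference of 0.17 (adjusted p = 4e-05, two-sided permutation test). That difference was 0.16 in replicate 1 and 0.19 in replicate 2. Among the highest 50% of scores in each list it came to -0.0077 and did not pass (permutation p = 0.85). Over whole sequences, X had a median score of 1.09 ± 0.02, above 2L (0.86 ± 0.04), 2R (0.91 ± 0.05), 3L (0.90 ± 0.01) and 3R (0.91 ± 0.03), and below chromosome 4 (1.21 ± 0.06; SD, n = 2 for each).

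Pooled over sequences, clusters on heterochromatin had higher scores than clusters on the large arms, and so did clusters on unplaced sequence. Median scores were 1.93 ± 0.03 on the heterochromatin of 2R, 1.80 ± 0.02 on that of 2L, 1.33 ± 0.13 on that of 3R and 1.14 ± 0.03 on that of 3L (SD, n = 2 for each). The heterochromatin of 2L held only 5 clusters in each replicate. That of 3R held 18 in replicate 1 and 19 in replicate 2, and that of 3L held 63 and 60. The heterochromatin of X was an exception at 0.94 ± 0.12 (SD, n = 2), below X itself at 1.09 ± 0.02, with 7 clusters in replicate 1 and 5 in replicate 2. The heterochromatin of 2R held the most clusters in the pool, 78 and 74, and single sequences were not tested. Heterochromatin is the compact, repeat-rich part of the chromosomes, and FlyBase r5 holds it partly as separate sequences named after the arm. The heterochromatin of 2R was covered over 19.6% ± 1.61, that of 3L over 15.7% ± 0.991, that of 2L over 11.9% ± 0.504, that of X over 10.8% ± 1.43 and that of 3R over 5.06% ± 0.376 (SD, n = 2 for each). Unplaced sequence, named U, was covered over 3.65% ± 0.194. Neither replicate had a cluster in the Y heterochromatin, where the combined list had 1. In replicate 1, the 171 heterochromatic clusters averaged a score of 1.57 ± 0.88 and the 5185 clusters of the large arms 1.14 ± 0.68 (SD over clusters), a difference of 0.44. In replicate 2, the 163 heterochromatic clusters averaged 1.63 ± 0.89 and the 5223 arm clusters 1.10 ± 0.66, a difference of 0.53. Clusters in U averaged 1.90 ± 0.85 and 1.94 ± 0.88. Each of these 4 differences from the arms passed the permutation test (adjusted p = 1e-05, the smallest it can give). Single clusters were permuted here, not blocks. The median cluster length, as a mean of the replicates, was 2878 to 3074 bp on the large arms and 2626 bp on U. On the heterochromatin it was 6819 bp for 2L, 4848 bp for 3R, 3408 bp for 2R, 2748 bp for 3L and 2530 bp for X. Longer clusters scored higher, and these differences were not tested within length classes. How the authors treated reads that match several places is not given in the sources used here.

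Coverage varied several-fold along the arms, in the same places in each replicate. The covered shares of 1 Mb blocks correlated between replicates with Pearson's r of 0.99 and Spearman's rho of 0.98 (119 blocks, permutation p = 1e-05 for each, the smallest it can give). The most covered block was the first of 2R, from position 1 to 1000000, at 38.7% ± 0.133 (SD, n = 2). It was followed by 2L from 19000001 to 20000000 at 35.3% ± 2.85 and by 2R from 1000001 to 2000000 at 34.9% ± 0.510. The least covered were on 3L: 4.26% ± 0.143 from 24000001 to 24543557, 6.27% ± 0.159 from 13000001 to 14000000 and 7.55% ± 0.156 from 5000001 to 6000000.

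**Figure D3:**
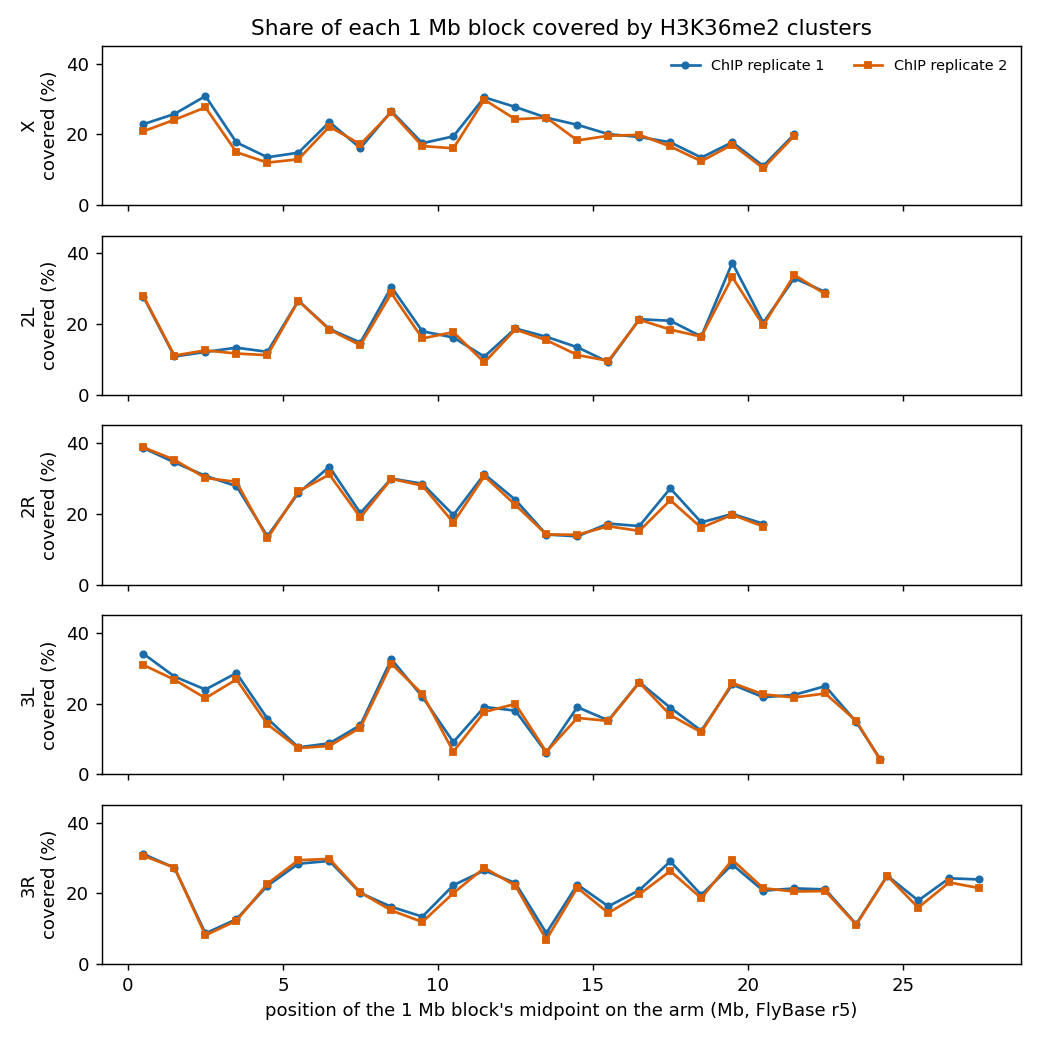
Percent of each 1 Mb block covered by clusters (y axis) against the block's midpoint in Mb (x axis), 1 panel per arm, 1 line per ChIP replicate. The lines follow each other closely, from 4.26% at the end of 3L to 38.7% at the start of 2R.

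The highest-scoring clusters covered in both replicates lay in heterochromatic or unplaced sequence. First was 2RHet from 1534199 to 1537265, with a score of 4.50 ± 0.29 in the replicates (SD, n = 2) and 5.07 in the combined list. In 2RHet a 43.2 kb cluster from 1543138 to 1586374 scored 3.73 ± 0.01. The other 3 lay in U, from 9586840 to 9589272 (3.93 ± 0.12), from 1985652 to 1987868 (4.07 ± 1.09) and from 7198507 to 7202082 (3.51 ± 0.24).

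The longest clusters covered in both replicates were broad domains. On X, a 76.4 kb domain from 21074382 to 21150818 scored 1.73 ± 0.34 and a 60.6 kb domain from 12172540 to 12233135 scored 2.82 ± 0.0018 (SD, n = 2). In 2RHet, domains of 58.6 kb from 1277711 to 1336282 and of 56.8 kb from 3127578 to 3184344 scored 3.06 ± 0.15 and 2.79 ± 0.12. On 2L, a 56.4 kb domain from 19806868 to 19863293 scored 1.97 ± 0.13. Each of these 5 domains was covered over at least 92.9% of its length in each replicate. Each was longer than the longest replicate 2 cluster (55481 bp), so no single replicate 2 cluster spanned a whole domain. The replicate scores are those of the cluster with the largest overlap. In replicate 2 that cluster spanned only part of the domain, so these scores do not describe the whole domain there.

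The top combined cluster was found in both replicates on X, 2R and 3L, and not on 2L, 3R or chromosome 4. On 2R it ran from 221976 to 268031 and scored 3.43 ± 0.06, on 3L from 9628404 to 9655386 at 3.25 ± 0.03, and on X from 16461214 to 16480434 at 3.20 ± 0.08 (SD, n = 2). On 2L it ran from 22285419 to 22286495 (combined score 3.64). On 3R, clusters from 4695321 to 4696324 and from 20035596 to 20036597 tied at a combined score of 3.26. These 3 clusters were shorter than the shortest replicate cluster and overlapped no cluster of either replicate. On chromosome 4, the cluster from 36147 to 38334 (combined score 3.15) overlapped a replicate 1 cluster and none of replicate 2.

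Long stretches of the arms held no cluster in any list. The longest ran from 13506970 to 13897505 on 3L (390.5 kb). It was followed by 383.2 kb on 2L from 15760770 to 16143925, 366.3 kb on 2L from 14606835 to 14973180, 359.7 kb on 3R from 23794562 to 24154291 and 343.9 kb on 3R from 12469995 to 12813910. In all, 217 stretches of 100 kb or more took up 35.7 Mb, or 30.0% of the 5 arms. Their share was 35.6% of 2L, 31.8% of X, 30.2% of 3R, 30.0% of 3L and 21.8% of 2R. Absence from the lists means that no region passed the authors' threshold, at a depth that is unknown.

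The combined list held clusters that neither replicate list had, most of them short and low in its score range. Of its 6396 clusters, 4694 overlapped both replicate lists, or 73.4% (72.3 to 74.5%), and their median score was 1.02. Another 558 overlapped replicate 1 only (median score 0.36) and 480 replicate 2 only (0.25). The remaining 664, or 10.4% (9.66 to 11.2%), overlapped neither, with a median length of 1263 bp and a median score of 0.33. Of these, 364 were shorter than 1301 bp, the shortest length in the replicate lists. In sequence, 79.8% of the combined list lay in both replicates and 5.51% in neither. Conversely, 54 replicate 1 clusters and 31 replicate 2 clusters had no overlap with the combined list.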

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

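The tests on the depletion regions and the 4 tests on X scores were chosen after the results were seen.

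The 16 regions named depletion in the combined list stood outside every comparison above, and 15 of them lay in clusters that replicate 2 names as enrichment. Replicate 1 clusters held 2 of them. Chance is argued against for the 15, since circular shifts gave 4.38 on average and 13 at most (one-sided permutation p = 1e-05, the smallest that 100000 shifts can give). The combined list is that of the replicate set, which includes replicate 2, so these lists are not independent. The shifts therefore cannot say why the regions lie there. The overlapped replicate 2 clusters all lay at or below percentile 2.78 of that list's scores, and in the combined list 0 regions named enrichment had a score under 0, and their lowest score was 0.00063, so the name may follow the sign of a score near 0 and need not mark a loss of signal. No biological explanation was tested, because the design has no group that would separate them.

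Clusters on X scored higher than autosomal clusters by 0.17, and longer clusters on X do not account for it, since the difference within each of 5 length classes averaged 0.16 (permutation p = 1e-04, the smallest that 10000 permutations can give). A constant added to every finished X score is argued against: the difference among the shortest 20% of clusters exceeded that among the longest 20% by 0.14 (permutation p = 0.011), with differences from the shortest to the longest class of 0.17 ± 0.02, 0.15 ± 0.01, 0.17 ± 0.0048, 0.26 ± 2.2e-05 and 0.03 ± 0.06 (SD, n = 2) that show no steady fall with length. Missed weak clusters are argued against as the whole cause on an X otherwise like the autosomal arms, since clusters above the autosomal median score were denser on X by 5.41 per Mb (permutation test, adjusted p = 0.0022). A partial loss stays open: total density differed by -0.30 (permutation p = 0.92) with the density before a loss unknown, and the score difference of -0.0077 among the highest 50% of scores (permutation p = 0.85) is what a loss of weak clusters would leave, although keeping high scores alone can also shrink a difference. A different input level on X could also play a role, and no biological explanation was tested.

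The combined list held 664 clusters found in neither replicate list. Its shorter minimum length is not the whole account, because 45.2% of them were as long as the shortest replicate cluster or longer. Their median score of 0.33 lay under the 25th percentile of the other combined clusters (0.46), and the median of the longer ones was 0.29. Regions that fall short of the threshold in a single replicate are thus a candidate explanation for the rest. Longer clusters had higher scores in the combined list (Spearman's rho 0.81), and scores were not compared at like length. Whether pooled reads or another way of combining produced them is not given in the sources used here.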

How the results depend on the processing

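The comparisons of chromosome 4, of X scores and of centromeres, with their alternatives, were chosen after the results were seen. A minimum length of 1 kb removed no cluster and tested nothing, so its 15 values are not counted here. Over 18 results and the other 85 alternatives, 62 kept direction and side of the threshold, or size. A count was called kept within a ratio of 1.5 of its main value. No paired analysis was possible because the input samples have no values in the lists, so ChIP and input replicates of one number cannot be compared. The comparisons by gene part, gene list and gene profile and their alternatives were not run, for want of an annotation on FlyBase r5. The highest 50% of each list by score left a mean of 2784.5 clusters by construction and lowered the covered share of the arms to 15.0%. It left 265 and 239 clusters unshared in replicates 1 and 2 and raised the overlapped shares to 90.5% and 91.4%. It also put 76.4% of combined clusters in both replicates with 315 in neither. Each list was cut at its own median, so a cluster whose partner fell under the other list's median counted as unshared. Against the full other list, 1.62% and 0.752% of the highest 50% in replicates 1 and 2 were unshared. With the highest 50% alone, the covered share of X turned to 1.24 percentage points above the autosomes (permutation p = 0.41). The score difference of X turned to -0.0077 (permutation p = 0.85). Keeping only clusters over the median can itself shrink a score difference, and why X was not higher among them was not tested. Merging clusters less than 1 kb apart lowered the mean number of clusters to 4605.5 and the unshared clusters to 460 in replicate 1 and 360 in replicate 2. It lowered the combined clusters in neither replicate to 447. These counts lay within the ratio of 1.5 and are among those called kept. Merging also gave overlapped shares of 90.1% and 92.1% and 77.2% of combined clusters in both replicates. Requiring an overlap of 50% gave 87.8% for replicate 1 and 72.1% for combined clusters in both replicates. The combined list covered 23.1% of the arms, and the cause was not tested. Leaving out combined clusters shorter than 1301 bp put 78.9% in both replicates and 300 in neither, a setting chosen after seeing the data. Keeping the regions named depletion, which was not planned either, put 665 in neither. With each replicate alone the number of clusters ranged from 5554 to 5583, the covered share from 19.9 to 20.8%, X minus autosomes from -0.79 to -0.16 points, its score difference from 0.16 to 0.19 and chromosome 4 minus the autosomal arms from 19.1 to 21.2 points. The Jaccard index stayed between 82.8% and 83.2%, and Spearman's rho between 0.90 and 0.93. Depth is unknown, so it cannot be said how many weak regions were missed.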

Other observations

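The test of coverage near centromeres was chosen after the block values were seen, and the test of random placement before.

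Clusters and cluster-free stretches were grouped along the arms beyond random placement. The longest stretch without a replicate 1 cluster was 395.2 kb, against 276.2 kb at most in 1000 random placements of the same clusters (permutation p = 0.001, the smallest they can give), and 16 stretches exceeded that maximum. In replicate 2 the longest was 482.3 kb against 258.8 kb at most, and 24 stretches exceeded it. Stretches in which reads could not be placed were not tested.

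Coverage was higher next to the centromere on 3 arms and lower on the other two. In the 2 Mb next to the centromere, 2R was covered over 36.8% ± 0.321 against 22.01% ± 0.559 on the rest of the arm, 2L over 31.3% ± 0.052 against 18.0% ± 0.575, and 3R over 29.1% ± 0.146 against 20.2% ± 0.483 (SD, n = 2). On X it was 14.9% ± 0.471 against 20.3% ± 1.01, and on 3L 14.6% ± 0.208 against 19.1% ± 0.649. The mean difference over the 5 arms was 5.42 percentage points (two-sided permutation p = 0.039 from 1000 circular shifts). The permutation test was also passed in the highest 50% of scores (6.70 points, p = 0.008), with merged clusters (5.46 points, p = 0.041) and without replicate 1 (5.82 points, p = 0.024). The permutation test was not passed with 1 Mb (3.85 points, p = 0.23), 3 Mb (3.34 points, p = 0.13) or 4 Mb (3.31 points, p = 0.1) next to the centromere, in the combined list (5.11 points, p = 0.063) or without replicate 2 (5.02 points, p = 0.052). The call thus depended on the distance and on the list used, and a general rise toward centromeres is not established by these lists.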
